A study of Mus musculus with 16 samples.

How the data were processed

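Transcript levels were measured on Affymetrix arrays in macrophage and dendritic cell progenitors (MDPs) and common monocyte progenitors (cMoPs), sorted by flow cytometry from the bone marrow of control (Dnmt1+/+) and Dnmt1c/chip mice. The series holds 16 arrays, 4 in each of 4 groups. The group of each array was taken from its source name and genotype labels, because the titles of the control cMoP arrays carry both genotype names. Replicate numbers were taken from the titles.

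The values used were log2 expression levels from the deposited series matrix, 1 per probe set and array. Per the submitters' processing notes, the tools involved were affy, RMA and limma. Their versions and settings are not given in the sources used here. RMA corrects background, applies quantile normalization and summarises probes on the log2 scale, and no further scaling was applied here for the main results. A second deposited table has 16 value columns whose names match no sample label, and it was not used.

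The table holds 41345 probe sets. Gene symbols came from the platform annotation supplied with the matrix: 23521 probe sets had 1 symbol, 1820 had several and 16004 had none. The design text names an earlier perfect-match mouse array, whereas the annotation lists numeric transcript cluster identifiers of another Affymetrix platform, so which probes stand behind a symbol rests on that annotation. Of the single-symbol probe sets, 23328 were found by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No genome build is given for the array, and the reference served only for names and for which genes neighbour each other. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over all arrays was used, which left 22180 genes. No filter on low values was applied for the tests, so a difference from a group mean below the array medians (3.43 to 3.62) is a lower limit.

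Differences were tested in R 4.3.3 with limma 3.58.1. One linear model with 4 group means was fitted to all 16 arrays (lmFit, eBayes with a prior of 4.72 degrees of freedom), so that the groups share 1 estimate of the spread. The 5 comparisons were c/chip against control in each cell type, cMoPs against MDPs in each genotype, and the difference between the genotype effects in cMoPs and in MDPs. P-values were adjusted by the Benjamini-Hochberg method across genes, with a threshold of 0.05. Standard errors (SE) are those of the moderated fit, and SDs are over the 4 arrays of a group. Sort markers and Dnmt1 were also tested with two-sided exact permutation tests over the 70 arrangements of 4 against 4 arrays, where the smallest possible p is 0.0286. Of 4 against 4 values, chance leaves 1 gene in 35 without overlap.

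A set of 18 gene lists holding 484 measured genes of 544 listed was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over all 90 tests. The lists covered DNA methylation factors, germline, imprinted and interferon genes, dendritic cell, MHC class II, monocyte, neutrophil granule, stem and progenitor, erythroid and megakaryocyte, B cell, T and NK cell, and basophil and mast cell genes, and cell cycle, p53, Myc and ribosome biogenesis, immediate early and stress, and heterochromatin genes. Camera with an estimated correlation and fry were alternatives. The lists, tests, naming rule and the first group of alternatives below were fixed before the data were examined. The rule named Dnmt1, the sort markers, the 8 genes with the largest differences in each direction among those past the threshold without overlap between arrays (4 for the cell types in c/chip mice), up to 4 members of each list past the threshold, and 6 genes of the interaction. Predicted and unnamed transcripts were passed over.

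Alternatives were all probe sets or their mean, removal of the genes with the lowest mean levels, quantile normalization, median centring, a trended and robust fit, array weights, a fit of only the 2 groups compared, a 2-fold minimum, replicate number as a block, and leaving out each array. After the data had been seen, fits were added without the pair of arrays farthest from their group means, without sex-linked genes, with Y-linked or immediate early levels as a covariate, and with replicate numbers 1 and 2 against 3 and 4 as a term. The gene test was tested on simulated data for the genotype comparison in MDPs, with 200 of 22180 genes changed: 10% of the genes changed by 0.5 on the log2 scale were recovered, 58% at 1, 98% at 2 and 100% at 3. Of 141 calls, 8 were unchanged genes. A simulated list of 30 genes shifted by 1 was called, and 0 unshifted lists were. The simulated genes varied independently, whereas estimated correlations within the real lists reached 0.55, so false list calls were not gauged by it. Each simulated gene also had the same spread in all groups. In the data, the SD around group means was 0.29 to 0.35 on MDP arrays and 0.23 to 0.34 on cMoP arrays. False gene calls that come from unequal spread were therefore not gauged either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A table of other probe sets, those with several or no symbols, was tested apart. The number of arrays limits the precision.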

Results

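Gene expression was measured on 16 arrays from sorted mouse bone marrow progenitors, with 4 arrays in each of 4 groups: control MDPs, Dnmt1c/chip MDPs, control cMoPs and Dnmt1c/chip cMoPs. MDPs are progenitors with macrophage and dendritic cell potential, and cMoPs are their descendants committed to the monocyte lineage. Both were sorted as lineage-negative, Kit-high, CD115-positive and CD11b-negative cells, and Ly-6C separated them, absent on MDPs and present on cMoPs. Dnmt1 encodes the maintenance DNA methyltransferase, and the c/chip genotype pairs a null allele with a hypomorphic one. The comparisons ask how reduced Dnmt1 changes transcripts in each progenitor and how the progenitors differ within each genotype. Values are log2 RMA levels, with array medians between 3.43 and 3.62. Mean correlations of an array with the others of its group lay between 0.972 and 0.987. Principal components were computed on the genes whose mean level over all arrays lay above the median of these means. The first component held 28.6% of the variance and separated MDP arrays (13.7 to 34.05) from cMoP arrays (−26.92 to −17.83). The second held 14.2% and separated control MDPs (9.28 to 28.43) from c/chip MDPs (−34.35 to −17.22). The labels do not say whether arrays came from separate animals, so p-values measure only the spread between samples.

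The sexes of the animals were mixed. Xist, the X-inactivation transcript, was at 10.791 to 11.36 in control replicates 1 and 2 of both cell types and at 3.577 to 4.29 in control replicates 3 and 4. Among c/chip cMoPs, replicate 1 had the high Xist level (10.897). Replicates 1, 3 and 4 of the c/chip MDPs carried both Xist (9.511 to 10.647) and Y-linked transcripts, whose mean was 5.271 to 6.422 there against 2.605 to 3.07 in the control MDPs with high Xist. No other array had both at high levels. These c/chip MDP arrays thus appear to hold material of both sexes, so of more than 1 animal, which the labels do not record. In MDPs the make-up of the samples therefore differed between genotypes.

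Dnmt1 itself was lower in c/chip cells. Its level was 9.86 ± 0.07 (SD, n = 4) in control MDPs and 8.75 ± 0.27 in c/chip MDPs, a log2 difference of −1.10 (SE 0.137, 2.15-fold lower, adjusted p = 3.48e-04). In cMoPs it was 9.78 ± 0.09 and 8.88 ± 0.14, a difference of −0.91 (SE 0.137, 1.87-fold lower, adjusted p = 0.0081). All 4 c/chip arrays lay below the control mean in both cell types, and exact permutation tests gave p = 0.0286, the smallest they can give. The 2 reductions differed by 0.20 (SE 0.194, adjusted p = 0.83). Of 18 measured DNA methylation factors, Dnmt1 passed in each genotype comparison and 17 did not. Adjusted over the list alone, 1 was higher and 3 were lower in MDPs, and 1 was lower in cMoPs. The list as a whole did not pass in either cell type (camera adjusted p = 0.209 and 0.153).

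Transcripts of the sorting markers followed the gates for Ly-6C. Ly6c2, one of its genes, was 1.84 higher on the log2 scale in control cMoPs than in control MDPs (SE 0.136, adjusted p = 3.53e-07), and Ly6c1 was 2.02 higher (SE 0.28, adjusted p = 2.40e-04). In c/chip MDPs, Ly6c2 was 11.27 ± 0.17, against 10.21 ± 0.26 in control MDPs (difference 1.06, SE 0.136, adjusted p = 4.72e-04) and 12.04 ± 0.05 in control cMoPs. Kit, Csf1r (CD115) and Itgam (CD11b) did not pass between genotypes in either cell type. Their differences in MDPs were 0.12 (SE 0.149), −0.47 (SE 0.157) and 0.22 (SE 0.248).

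**Figure D1:**
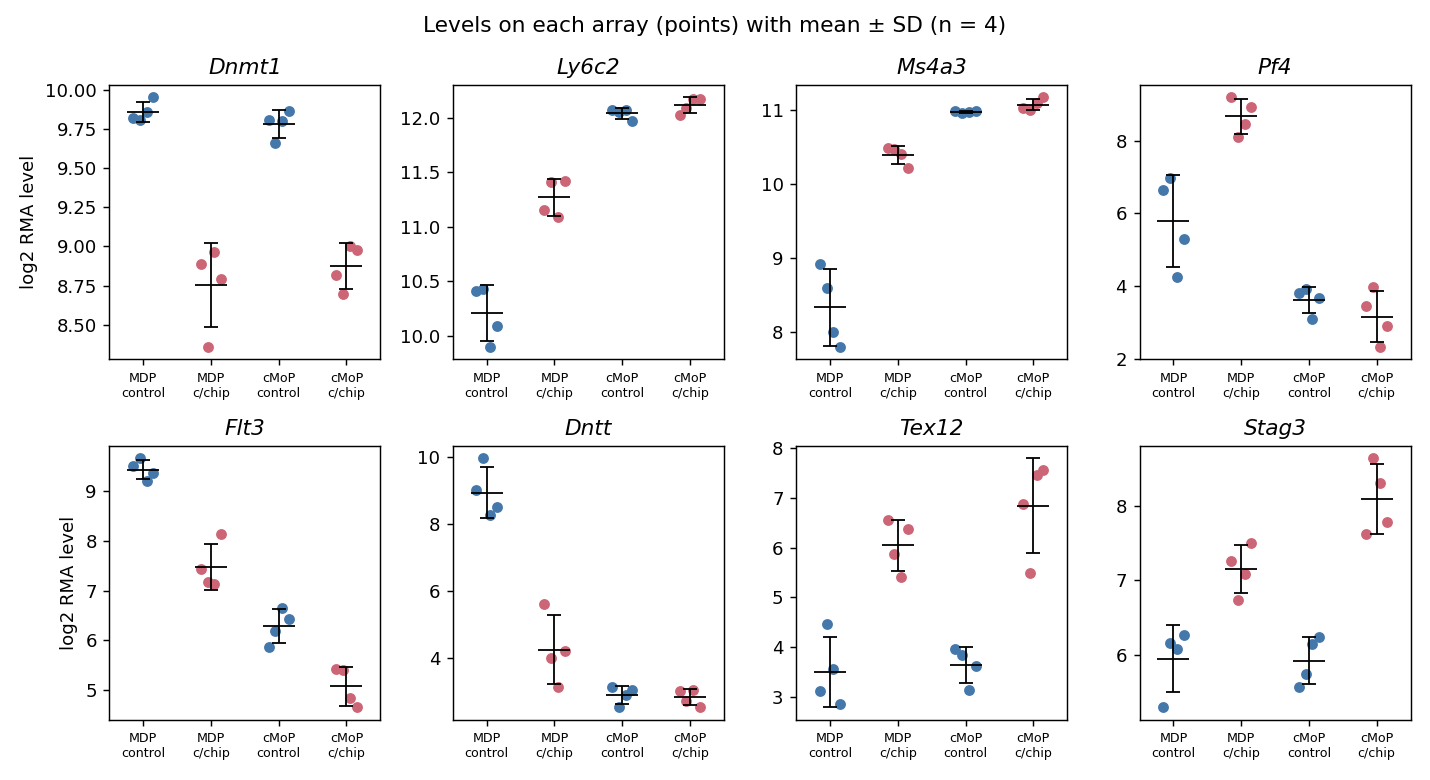
Log2 RMA levels of 8 genes on each of 16 arrays, with the mean and SD of each group of 4 as black bars, control in blue and c/chip in red; vertical axes differ between genes and do not start at 0. Dnmt1 is lower and Tex12 and Stag3 are higher in c/chip cells of both types, and Dntt is lower and Pf4 and Ms4a3 are higher in c/chip MDPs.

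In c/chip MDPs, 12 of 30 neutrophil granule genes were higher and 4 of 30 dendritic cell genes lower than in control MDPs. Dntt, the template-independent DNA polymerase of lymphoid progenitors, fell from 8.94 ± 0.76 to 4.25 ± 1.03 (log2 difference −4.68, SE 0.409, 25.7-fold lower, adjusted p = 1.81e-05). The interleukin 7 receptor gene Il7r was 3.17 lower on the log2 scale (SE 0.472, adjusted p = 0.002), and Siglech, a marker of plasmacytoid dendritic cells, was 2.75 lower (SE 0.394, adjusted p = 0.0014). Among the largest rises were Pf4, the platelet factor 4 gene (log2 2.89, SE 0.478), Cpa3, a mast cell carboxypeptidase (2.74, SE 0.368), Selp, P-selectin (2.65, SE 0.425), Gp5, a platelet glycoprotein (2.48, SE 0.257), and the transcription factor gene Gata2 (2.44, SE 0.378), with adjusted p from 4.97e-05 to 0.0048. Slc25a31, a sperm-type ADP/ATP carrier gene, and Tex12, a meiosis gene, were higher by 3.08 (SE 0.448) and 2.56 (SE 0.415). Further down, the falls were −2.58 for the small nucleolar RNA Snord71, −2.48 for Cmah, −2.24 for Klk8, −2.09 for Cd300c and −2.07 for Adam2. In total 280 genes were higher and 152 lower, of which 147 and 67 changed at least 2-fold. The call of Ltf (lactoferrin, 2.68 higher, SE 0.63) was lost in 9 of 16 fits that left out 1 array (adjusted p up to 0.0993).

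By list, the neutrophil granule genes moved most in MDPs. Of 30 measured, 12 were higher, 0 lower and 18 did not pass, and adjusted over the list alone 24 were higher. The median difference was 1.47 (camera adjusted p = 2.99e-25, and 0.0215 with an estimated correlation). Ms4a3, a gene of granulocyte and monocyte progenitors, was 2.06 higher (SE 0.189) and Nkg7, a granule membrane protein gene, 3.99-fold higher (SE 0.158 on the log2 scale). Of 22 erythroid and megakaryocyte genes, 6 were higher and 1 lower (16 and 1 adjusted over the list alone, median 1.06), and the camera call (adjusted p = 1.57e-12) was lost with an estimated correlation (adjusted p = 0.124). Pf4 and Gp5 belong here. Of 18 basophil and mast cell genes, 5 were higher, among them Cpa3 and Hdc, the histidine decarboxylase gene (2.04, SE 0.269). The same 5 calls came when adjusted over the list alone (median 0.59, camera adjusted p = 5.79e-05, and adjusted p = 0.166 with an estimated correlation). Of 31 stem and progenitor genes, 3 including Gata2 were higher and 1, the transcription factor gene Sox4 (−0.84, SE 0.16), was lower (4 and 2 adjusted over the list alone). That list's call (adjusted p = 0.0188) was lost with an estimated correlation (adjusted p = 0.265) and without c/chip replicate 1 (adjusted p = 0.102).

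Of 30 dendritic cell genes, 4 were lower in c/chip MDPs and none higher (5 adjusted over the list alone, median −0.23, camera adjusted p = 3.93e-05, and 0.0439 with an estimated correlation). Flt3, the receptor that drives dendritic cell development, fell by 1.96 (SE 0.236, adjusted p = 2.71e-04). Irf8, a transcription factor of monocyte and dendritic cell fate, was 0.58 lower (SE 0.128, adjusted p = 0.0278), and its call was lost in 6 of 16 fits without 1 array (adjusted p up to 0.0774). Of 21 B cell genes, Dntt and Il7r were lower and the other 19 did not pass, with the same counts adjusted over the list alone. The list's call (median −0.03, adjusted p = 0.0483) was lost with an estimated correlation (adjusted p = 0.137) and in 10 of 16 fits without 1 array. Of 22 T and NK cell genes only Gzmb, granzyme B, passed (2.35 higher, SE 0.341, adjusted p = 0.0015), and 2 were higher adjusted over the list alone (list adjusted p = 0.386). Of 41 monocyte genes, 5 including Ly6c2 and Fcgr3 (1.65, SE 0.306) were higher and 1 lower (10 and 2 adjusted over the list alone), and the list did not pass (median 0.04, adjusted p = 0.153). The 9 MHC class II genes gave no call in MDPs, also adjusted over the list alone (median −0.17, adjusted p = 0.15).

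Of 38 cell cycle genes, 2 including Kif23, a cytokinesis motor gene (−0.95, SE 0.158), were lower (2 higher and 5 lower adjusted over the list alone, median −0.06), and of 28 Myc and ribosome biogenesis genes 2 including Srm, spermidine synthase (0.82, SE 0.126), were higher (4 adjusted over the list alone, median 0.15). Of 21 heterochromatin genes, Dnmt1 alone was lower (2 adjusted over the list alone, median −0.18). The camera calls of these 3 lists (adjusted p = 0.0188, 0.0124 and 0.0029) were lost with an estimated correlation (adjusted p = 0.402, 0.517 and 0.129). The first was also lost without control MDP replicate 4 or c/chip MDP replicate 3 (adjusted p up to 0.205), and the second without control MDP replicate 2 or c/chip MDP replicate 1 (adjusted p up to 0.0596). Of 33 imprinted genes 0 passed (1 higher and 1 lower adjusted over the list alone), with 3169 of all genes at an unadjusted limma p under 0.05. Of 30 interferon genes 1, Xaf1, passed (0.79, SE 0.177, adjusted p = 0.0309), a call lost in 5 of 16 fits without 1 array (adjusted p up to 0.0836), and 3 were higher and 1 lower adjusted over the list alone. None of 28 p53 target genes passed, also adjusted over the list alone (list adjusted p = 0.524). None of 23 immediate early and stress genes passed either, also adjusted over the list alone, but their median was −0.91 in c/chip MDPs (camera adjusted p = 1.28e-05, and adjusted p = 0.416 with an estimated correlation). The mean level of that list varied within groups by a pooled SD of 0.728 in MDPs. Over both cell types it was 7.066 to 7.88 on arrays with replicate numbers 1 and 2 and 5.353 to 7.052 on those with numbers 3 and 4.

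The count of genes in this comparison rested on the pooled spread and on single arrays. It was 64 in a fit of the 8 MDP arrays alone, of which 63 were among the 432, and 264 with array weights. Without control replicates 3 or 4 it was 214 and 255, and without c/chip replicates 1 or 4 it was 270 and 262. Of the 432 genes, 390 had no overlap between the 4 c/chip and the 4 control arrays, and 7% of all genes showed no overlap, against 2.86% by chance.

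**Figure D2:**
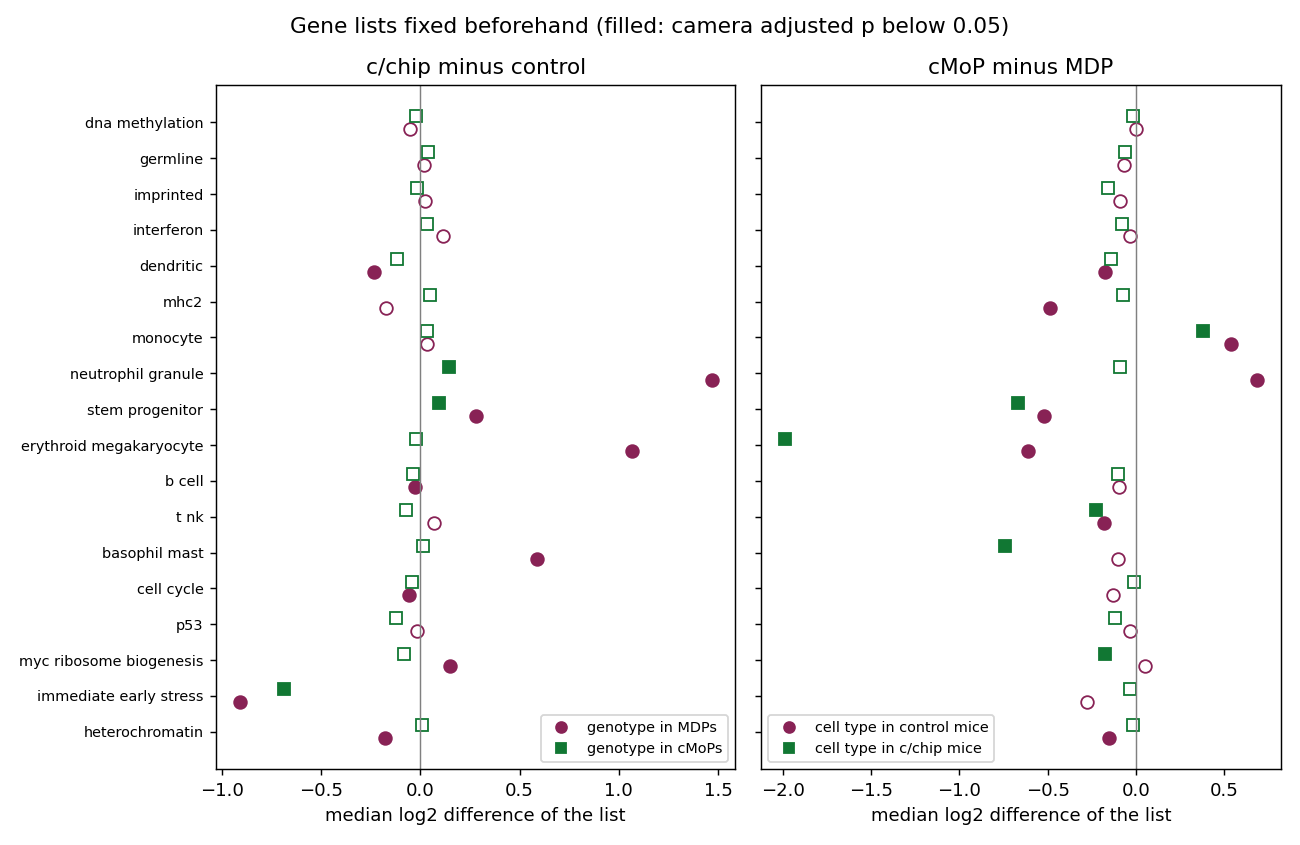
Median log2 difference of each of 18 gene lists between genotypes (left) and between cell types (right), with circles for MDPs or control mice and squares for cMoPs or c/chip mice, and filled symbols where camera with the preset correlation passed an adjusted p of 0.05. The neutrophil granule median is 1.47 between genotypes in MDPs and 0.14 in cMoPs, and the erythroid and megakaryocyte median is −1.99 between cell types in c/chip mice.

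In cMoPs, 15 genes were higher and 10 lower in c/chip cells, and Tex12 had the largest difference of the named genes. Tex12, a component of the synaptonemal complex that joins meiotic chromosomes, rose from 3.64 ± 0.37 to 6.85 ± 0.95 (log2 difference 3.21, SE 0.415, 9.28-fold, adjusted p = 0.0025). Stag3, a meiotic cohesin subunit gene, was 2.18 higher (SE 0.257, adjusted p = 0.001), the growth factor gene Clec11a 2.60 higher (SE 0.203, adjusted p = 1.02e-05), and Rpl39l, a testis-enriched ribosomal protein gene, 2.59 higher (SE 0.284, adjusted p = 7.51e-04). The class I gene H2-Q5 and the Schlafen gene Slfn4 were 2.14 (SE 0.278) and 1.76 (SE 0.25) higher. The protease gene Klk8 was 2.53 lower (SE 0.288, adjusted p = 8.41e-04), Ncam1, a neural adhesion molecule gene, 2.02 (SE 0.285), the cathepsin gene Ctsf 2.01 (SE 0.277) and the ubiquitin ligase gene Rnf43 1.53 (SE 0.222). All 25 genes had no overlap between the genotypes' arrays, against 3.87% of all genes and 2.86% by chance. Adam19, Gpc3, Ephx2 and Slc7a2, lower by 1.38 to 0.94, lost their calls in 7, 6, 7 and 10 of 16 fits without 1 array (adjusted p up to 0.175). Slc25a31 (2.63, SE 0.448) and the meiosis gene Hormad2 (2.18, SE 0.352) each lost their call in 4 of 16 fits without 1 array (adjusted p up to 0.0883 and 0.0826). The count was 60 with array weights, 15 without control cMoP replicate 1, 15 without control cMoP replicate 3 and 16 without c/chip cMoP replicate 4.

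The germline list held the called genes of the lists in cMoPs other than Dnmt1. Of 37 measured germline genes, 2 were higher in c/chip cMoPs (4 adjusted over the list alone), and 3 in c/chip MDPs (4 adjusted over the list alone), where Slc25a31 led (3.08) and the call of Syce1 (1.85, SE 0.459) was lost in 13 of 16 fits without 1 array (adjusted p up to 0.1023). The list as a whole did not pass (medians 0.04 and 0.02, camera adjusted p = 0.0584 and 0.418). The neutrophil granule list (median 0.14, adjusted p = 0.0129) and the stem and progenitor list (median 0.10, adjusted p = 0.0082) passed in cMoPs with 0 members called over all genes and 0 and 4 adjusted over the list alone, and both were lost with an estimated correlation (adjusted p = 0.517 and 0.21). The first was also lost without c/chip cMoP replicate 3 (adjusted p = 0.0628) and the second without control cMoP replicate 2 (adjusted p = 0.0919). The unadjusted limma p was under 0.05 for 1052 genes. Flt3 was 1.20 lower in c/chip cMoPs (SE 0.236), which did not pass over all genes (adjusted p = 0.0712) and was the 1 dendritic gene lower when adjusted over the list alone. The median of the immediate early and stress list was −0.69 in cMoPs too (adjusted p = 6.36e-06, and adjusted p = 0.402 with an estimated correlation), with a pooled within-group SD of 0.86. Its members gave 0 calls.

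A total of 14 genes passed in both cell types, all in the same direction, 10 higher and 4 lower in c/chip cells. For independent lists 0.487 genes were expected (Fisher's exact test p = 3.36e-18). Both comparisons used the same spread estimate for each gene, and genes are correlated. The lists are therefore not fully independent, and this p may be too small. The higher ones were Tex12, Slc25a31, Hormad2, Stag3, Rpl39l, Clec11a, Car3, Tnnt1, 1700006J14Rik and Gm20756, and the lower ones were Dnmt1, Klk8, Ctsf and Gpc3. Car3, Tnnt1, 1700006J14Rik and Gm20756 lay outside the naming rule and are given to complete the overlap. The calls of Hormad2 in MDPs and Gpc3 in cMoPs were each lost in 6 of 16 fits without 1 array (adjusted p up to 0.0809 and 0.107). All 25 genes called in cMoPs had the same sign in MDPs. Across all genes, which are not independent replicates, the 2 genotype differences correlated with r = 0.179. The overlap was 7 in fits of only the 2 groups compared, and it was 9 without control cMoP replicate 1, 8 without control cMoP replicate 3 and 9 without c/chip cMoP replicate 4.

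**Figure D3:**
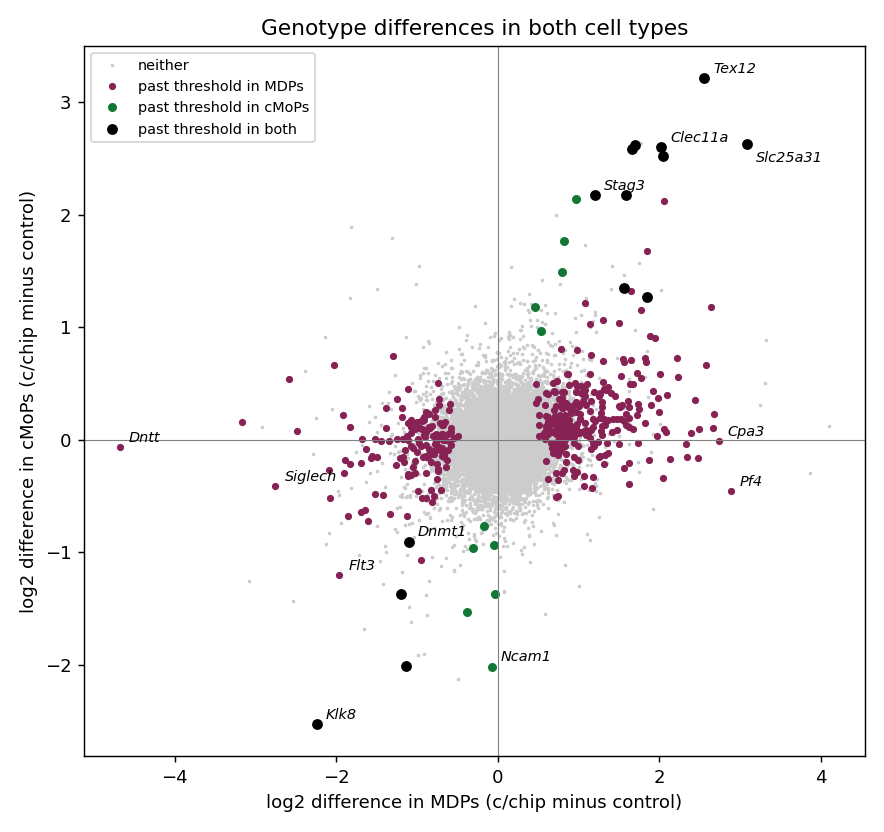
Log2 difference between c/chip and control cells in MDPs (horizontal) and in cMoPs (vertical), 1 point per gene, with the 14 genes past the threshold in both cell types in black. Tex12, Slc25a31, Clec11a and Stag3 are higher and Klk8 and Dnmt1 lower in both, while Dntt, Pf4 and Cpa3 (−4.68, 2.89 and 2.74 in MDPs) are at −0.07, −0.46 and −0.01 in cMoPs.

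The genotype effect itself differed between cell types for 13 genes by the interaction test, 3 with a more positive and 10 with a more negative effect in cMoPs. Dntt passed (4.61, SE 0.578, adjusted p = 0.0042), but in cMoPs of both genotypes (2.91 ± 0.27 in control) it lay below every array's median, where a fall could not be measured. Gp5 (−2.64, SE 0.364, adjusted p = 0.0067) and Ms4a3 (−1.97, SE 0.267, adjusted p = 0.0067) rose in MDPs and were not called in cMoPs (−0.16, SE 0.257, and 0.095, SE 0.189). Ms4a3 was already at 10.962 to 10.997 in control cMoPs, with array maxima of 12.93 to 13.33. Whether a further rise would show in full at that level was not tested. Cmah (2.56, SE 0.398, also near the array medians in cMoPs), Hdc (−2.39, SE 0.38) and Cd300c (1.82, SE 0.283) passed as well, but lost their calls in 4, 6 and 4 of 16 fits without 1 array (adjusted p up to 0.0616, 0.0655 and 0.0616). The neutrophil granule list differed between the cell types (4 genes called, 14 adjusted over the list alone, median −1.34, adjusted p = 5.66e-17, and 0.0439 with an estimated correlation). The erythroid and megakaryocyte list (1 called, 5 adjusted over the list alone, median −1.03, adjusted p = 3.50e-10) lost its call with an estimated correlation (adjusted p = 0.137). The basophil and mast cell list (median −0.48, adjusted p = 0.0018), the Myc and ribosome biogenesis list (−0.23, 0.0032), the dendritic list (0.14, 0.0101) and the heterochromatin list (0.18, 0.0188) also passed, and with an estimated correlation all 4 were lost (adjusted p = 0.265, 0.432, 0.165 and 0.188). Without control MDP replicate 2 the dendritic and heterochromatin lists had adjusted p up to 0.0596, and the heterochromatin call was also lost without control cMoP replicate 2 or c/chip cMoP replicate 3. The count of 13 was 33 without c/chip MDP replicate 3, 26 without c/chip MDP replicate 4, 5 without control cMoP replicate 1, 7 without control cMoP replicate 4, and 8, 5 and 5 without c/chip cMoP replicates 1, 2 and 4.

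Between cell types in control mice, 17 of 41 monocyte genes were higher and 12 of 31 stem and progenitor genes lower in cMoPs. In total 631 genes were higher and 380 lower in cMoPs than in MDPs, 295 and 184 of them at least 2-fold. The largest rises were Mgam (log2 4.03, SE 0.392), Gda (3.94, SE 0.337), Mcemp1 (3.88, SE 0.414), Sgms2 (3.86, SE 0.392), the ficolin gene Fcnb (3.80, SE 0.746), Trem3 (3.79, SE 0.306), Far2 (3.76, SE 0.394) and Aoah (3.63, SE 0.365), with adjusted p from 9.59e-07 to 0.0049. Dntt was 6.03 lower (SE 0.409, adjusted p = 1.63e-07), a lower limit because its cMoP level lay below every array's median, and the carbonic anhydrase gene Car1 5.18 lower (SE 0.538, 36.2-fold, adjusted p = 1.26e-05). Fads2, Ctla2a, Il7r, Car2, Emp1 and Bpifc were lower by log2 differences from −3.78 to −3.55. Of 41 monocyte genes, 17 were higher and 1 lower (20 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 1.16e-09, and 0.0439 with an estimated correlation), among them Klf4, a transcription factor gene of monocyte differentiation (2.68, SE 0.287), and Fcgr3 (1.91, SE 0.306). Of 31 stem and progenitor genes, 12 were lower and 0 higher (18 lower adjusted over the list alone, median −0.52, adjusted p = 1.50e-19, and 0.0022 with an estimated correlation), led by Gfi1b (−2.84, SE 0.444), Angpt1 (−2.84, SE 0.231) and Sox4 (−2.34, SE 0.16). No replicate left out moved the count of 1011 outside 683 to 1114.

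In the same comparison, 10 of 30 neutrophil granule genes were higher, including Elane, neutrophil elastase (2.37, SE 0.142), and Hp, haptoglobin (2.58, SE 0.275). Adjusted over the list alone, 17 were higher and 1 lower. That list's call (median 0.69, adjusted p = 1.17e-13) was lost with an estimated correlation (adjusted p = 0.0733). Of 22 erythroid and megakaryocyte genes, 6 were lower (10 adjusted over the list alone, median −0.61, adjusted p = 1.16e-08, and adjusted p = 0.165 with an estimated correlation). Of 30 dendritic cell genes, 6 were lower and 1, Klf4, higher (7 and 2 adjusted over the list alone, adjusted p = 0.0022, and adjusted p = 0.129 with an estimated correlation), with Flt3 3.15 lower (SE 0.236) and Itgax, which encodes CD11c, 2.06 (SE 0.254). Of 9 MHC class II genes, 3 were lower (also 3 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.129 with an estimated correlation). They were H2-Aa, H2-Ab1 and H2-Ob, whose calls were lost in 8, 2 and 1 of 16 fits without 1 array (adjusted p up to 0.115, 0.0592 and 0.0568). Of 21 B cell genes, Dntt, Il7r and Rag2 (−2.34, SE 0.465) were lower (1 higher and 3 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.0587). The T and NK cell list (median −0.18, adjusted p = 0.0381) and the heterochromatin list (median −0.15, adjusted p = 0.0202) passed, with 1 and 0 genes lower (1 and 2 adjusted over the list alone). Both were lost with an estimated correlation (adjusted p = 0.166 and 0.193). The first was also lost without control MDP replicate 3 or control cMoP replicates 3 or 4 (adjusted p up to 0.0818), and the second without control MDP replicates 1 or 2 or control cMoP replicate 2 (adjusted p up to 0.0677). Peg13 was the 1 imprinted gene called (−1.49, SE 0.213), also adjusted over the list alone (list adjusted p = 0.173).

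In c/chip mice, 16 of 22 erythroid and megakaryocyte genes were lower in cMoPs than in MDPs. Compared with c/chip MDPs, 399 genes were higher and 331 lower in c/chip cMoPs, 194 and 203 of them at least 2-fold. After median centring of each array the counts were 507 and 264, and after quantile normalization 360 and 355. Car1 was 5.85 lower in cMoPs (SE 0.538, 57.5-fold, adjusted p = 7.89e-06), Cpa3 5.74 (SE 0.368), Pf4 5.51 (SE 0.478) and Car2 4.84 (SE 0.477). Of 22 erythroid and megakaryocyte genes, 16 were lower and 0 higher (20 lower adjusted over the list alone, median −1.99, camera adjusted p = 5.22e-27, and 0.0215 with an estimated correlation). Of 31 stem and progenitor genes, 13 were lower (19 adjusted over the list alone, median −0.67, adjusted p = 3.58e-21, and 0.0022 with an estimated correlation), among them Gfi1b (−4.41, SE 0.444) and Angpt1 (−3.71, SE 0.231). Of 18 basophil and mast cell genes, 3 including Mcpt8, a mast cell protease gene (−1.27, SE 0.251), were lower (8 adjusted over the list alone, adjusted p = 3.94e-05, and adjusted p = 0.166 with an estimated correlation). The largest rises were Mgam (3.07, SE 0.392), Klf4 (2.98, SE 0.287), the ribonuclease gene Rnase2a (2.80, SE 0.255) and the lectin gene Mgl2 (2.78, SE 0.337). Of 41 monocyte genes, 10 were higher and 1 lower (15 and 1 adjusted over the list alone, median 0.38, adjusted p = 1.71e-10, and 0.0405 with an estimated correlation).

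The neutrophil granule list did not separate c/chip cMoPs from c/chip MDPs (camera adjusted p = 0.407). Of 30 genes, 4 including Igsf6 (1.25, SE 0.16) were higher and 2 were lower, Mmp8 (−1.46, SE 0.256) and Ltf (−2.77, SE 0.63), whose call was lost without c/chip cMoP replicates 3 or 4 (adjusted p up to 0.0725). Adjusted over the list alone, 7 were higher and 7 lower. The list's median (−0.09) and mean (−0.47) were below 0 although camera's direction was upward. Of 22 T and NK cell genes, Gzmb (−4.02, SE 0.341) and Lat (−2.90, SE 0.375) were lower (also 2 adjusted over the list alone, adjusted p = 0.0088, and adjusted p = 0.125 with an estimated correlation). The Myc and ribosome biogenesis list, with 1 gene lower (also 1 adjusted over the list alone), had a median of −0.18 (adjusted p = 0.0188, and adjusted p = 0.541 with an estimated correlation), and lost its call without c/chip MDP replicate 1 or c/chip cMoP replicate 2 (adjusted p up to 0.182). Of 18 DNA methylation factors, Tet2 was 1.08 higher (SE 0.21, adjusted p = 0.0073) and Dnmt3a 0.66 lower (SE 0.159, adjusted p = 0.0293), a call lost in 7 of 16 fits without 1 array (adjusted p up to 0.0876). Adjusted over the list alone, 1 was higher and 3 lower (list adjusted p = 0.803). Of 33 imprinted genes, Kcnq1ot1 was 1.44 higher (SE 0.235), and Peg13 and Phlda2 were 1.27 (SE 0.213) and 0.73 lower (SE 0.188), the latter call lost in 11 of 16 fits (adjusted p up to 0.107). Adjusted over the list alone, 1 was higher and 3 lower (list adjusted p = 0.0743). The count of 730 was 482 in a fit of only these 8 arrays and 437 without c/chip cMoP replicate 3. Both cell type comparisons called 336 genes, 333 in the same direction, against 33.3 expected for independent lists, and across all genes the differences correlated with r = 0.523. These comparisons also used the same spread estimate for each gene, so the lists are not fully independent. For 3 genes the directions were opposite. Groups did not overlap for 10.78% of all genes in control and 10.05% in c/chip mice, against 2.86% by chance.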

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

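The tests of cell admixture, of other cell types alike, of sex and of handling were chosen only after the result was seen, whereas the counts over other splits of the arrays were planned.

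The genotype effect differed between cMoPs and MDPs for 13 genes by the interaction test. As the effect in cMoPs minus that in MDPs, the log2 values were 4.615 for Dntt, 2.558 for Cmah, 1.82 for Cd300c, −2.636 for Gp5, −2.388 for Hdc, −1.969 for Ms4a3, −1.748 for Nkg7, −1.58 for Elane, −1.417 for Emilin2, −1.349 for Gstm1, −1.245 for Gm1604b, −1.094 for Srm and −1.071 for Gsr. The values for Dntt and Cmah cannot be read as absent effects in cMoPs, because there Dntt lay below every array's median in both genotypes and Cmah near the medians, where a fall could not be measured. Elane and Ms4a3 were high in control cMoPs (12.067 to 12.108 and 10.962 to 10.997, with array maxima of 12.93 to 13.33). Whether a further rise there would show in full was not tested. A total of 6 lists differed in the same test, with medians of 0.142 for dendritic genes, −1.338 for neutrophil granule genes, −1.027 for erythroid and megakaryocyte genes, −0.48 for basophil and mast cell genes, −0.234 for Myc and ribosome biogenesis genes and 0.184 for heterochromatin genes. Of these the neutrophil granule list held with an estimated correlation (adjusted p = 0.0439). The count of 13 was 33 without c/chip MDP replicate 3, 26 without c/chip MDP replicate 4, 5 without control cMoP replicate 1, 7 without control cMoP replicate 4, and 8, 5 and 5 without c/chip cMoP replicates 1, 2 and 4.

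Of the 35 splits of the 8 arrays, 1, the real one, gave as many genes in each of the 4 comparisons of groups. That is the smallest share that 35 splits can give, so it argues against chance but does not exclude it. The other splits also mix the real groups, which widens the spread of the genes that differ and lowers their counts. The real counts of 432, 25, 1011 and 730 stood against highest other counts of 8, 1, 2 and 2. For the interaction, 4 of 100 drawn permutations, the real one included, gave 13 genes or more, and the highest other count was 77. The 3 draws with more genes (77, 23 and 16) kept or swapped the genotype of all 8 MDP arrays, and no other draw did. They carry the genotype difference in MDPs, which the remaining draws break up. The 4 of 100 therefore cannot separate an interaction from a genotype effect in MDPs, and it lends the count of 13 no support.

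The pattern of c/chip MDPs with higher granule and erythroid and megakaryocyte genes and lower Dntt, Il7r and Flt3 was weighed against cells of another kind in the sorted fraction. The erythroid and megakaryocyte list rose in c/chip MDPs (median 1.065, bootstrap SE 0.137) but is lower in cMoPs. The tables therefore argue against cMoPs within the gate as the source of that rise. A lower MDP share with more of every other cell type alike was not decided. The neutrophil list median exceeded the B cell one by 1.495 (SE 0.246). However, the B cell list's median level was 3.23, below every array's median, where a small rise might not show. Both SEs come from resampling genes and do not measure the spread between samples. Genes within the neutrophil and erythroid lists were correlated (estimated 0.22 and 0.33). Sex is argued against as the whole cause, since 81.5% of the 432 genes stayed called with the Y-linked level as a covariate. With the immediate early level, 12 of 12 neutrophil genes and 18 of all 21 genes of the pattern did, but only 239 of the 432. These genes were picked because they were called. Their calls argue against handling only as far as the immediate early level tracks it. Epor, Itga2b and Vwf, at 0.997, 0.818 and 1.012 with SE 0.242, 0.196 and 0.239, lost their calls at 1.07, 0.866 and 1.094 because the SE rose to 0.269, 0.219 and 0.264. For the granule genes as a list, cMoPs that escape the Ly-6C gate cannot be told apart from a change within MDPs. Elane was at 9.72, 11.39 and 12.08 in control MDPs, c/chip MDPs and control cMoPs. The levels exceeded a mixture with 45.7% cMoPs by 0.38 (bootstrap SE 0.225 over genes), with 23 of 30 genes above it. Over 6 splits the implied shares were 0.279 to 0.318 from genes higher in cMoPs and 0.369 to 0.457 from genes lower (smallest difference −0.064). Single members differed from Elane. Ltf was at 3.58, 6.26 and 3.25 in the same groups, above both sources, though its call was lost in 9 of 16 fits without 1 array. Adjusted over the list alone, 7 genes were lower and 7 higher in c/chip cMoPs than in c/chip MDPs. An effect of Dnmt1 on MDPs, a shifted gate and a specific contaminating progenitor, which lineage depletion would remove only if marked, also stay open as hypotheses. So does the make-up of the samples, which differed between genotypes in MDPs and which these covariates do not settle.

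Among probe sets without a single gene symbol, which no comparison above uses, 51 passed between genotypes in MDPs and 10 in cMoPs.

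A single array stood far from the other 3 of its group for 34 of 548 pairs of gene and group, and chance alone gives about 27.4. In control MDPs these were Aoah in replicate 2 (4.48, others 3.16 to 3.2), Gzmb in replicate 2 (5.34), Fcgr3 in replicate 1 (4.05), Cd68, Cdkn1a and S100a6 in replicate 3 (7.95, 6.73 and 6.05), and Kit and Ms4a2 in replicate 4 (9.31 and 4.32). In c/chip MDPs they were Ddit4 and Srm in replicate 1 (5.75 and 10.27), Fcgr3, Nusap1 and S100a4 in replicate 3 (4, 7.11 and 7.42) and Kcnq1ot1 in replicate 4 (4.99). In control cMoPs they were Klk8 and Zbtb4 in replicate 1 (7.78 and 2.99), Car2, Gbp3, Nkg7 and Rian in replicate 2 (2.45, 5.91, 10.39 and 2.66), Csf1r, Egr1 and Sycp1 in replicate 3 (9.41, 3.72 and 4.13) and Ly6c2 in replicate 4 (11.97). In c/chip cMoPs they were Bank1, Hspa1a and Selp in replicate 1 (3.27, 4.64 and 6.12), Cbx5, E2f1, Hp and Ikzf2 in replicate 2 (8.92, 6.16, 10.12 and 4.37), Aoah in replicate 3 (8.15), and Fcnb and H2-Ob in replicate 4 (6.72 and 3.13).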

How the results depend on the processing

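The fits without the pair of arrays in doubt, without sex-linked genes, with Y-linked or immediate early levels as a covariate, and with replicate numbers 1 and 2 against 3 and 4 as a term were chosen only after the result was seen. The lower Dnmt1 level passed under every alternative run (−1.175 to −0.974 and −0.949 to −0.846 over single arrays left out of MDPs and cMoPs). The 432 genes between genotypes in MDPs became 264 with array weights, 64 in a fit of only the 2 groups compared and 214 with a 2-fold minimum, which removes smaller changes by construction. The fit of 2 groups has fewer degrees of freedom, but it gave 26 genes in cMoPs and 836 between cell types in control mice. It also leaves out the spread of the cMoP arrays. The SD around group means was 0.29 to 0.35 on MDP arrays and 0.23 to 0.34 on cMoP arrays. What lowered the count to 64 was not tested. The 25 genes in cMoPs became 60 with array weights. The cell type counts of 1011 and 730 became 479 and 397 with the 2-fold minimum, and the second 482 in a fit of only its 2 groups. Of 33 list calls, 8 held with an estimated correlation and 22 with fry, which made 26 calls in all (11 lost, 4 new). The overlap of 14 genes was 7 with only the 2 groups compared and 9 with the immediate early covariate, and that of 333 genes between cell type comparisons was 188 with the 2-fold minimum. The cause was not tested for array weights, the estimated correlation or the covariate. Over single arrays left out, the counts were 214 to 505 in MDPs (214 and 255 without control MDP replicates 3 and 4, 270 and 262 without c/chip MDP replicates 1 and 4), 15 to 28 in cMoPs (15 without control cMoP replicates 1 or 3, 16 without c/chip cMoP replicate 4), 683 to 1114 and 437 to 761 between cell types (437 without c/chip cMoP replicate 3), 5 to 33 for the interaction, 29 to 37 for list calls, and 8 to 14 and 233 to 327 for the overlaps (9 and 8 without control cMoP replicates 1 and 3, 9 without c/chip cMoP replicate 4). As a replicate block, the replicate number gave 389, 26, 1011, 702 and 12 genes. Of these, 337, 21, 903, 630 and 9 were among the main calls, and 7 named gene calls were lost and 6 gained. Between genotypes, same-numbered arrays correlated by 0.032 to 0.186 in cMoPs (own number best for 3 of 4) and −0.039 to 0.093 in MDPs (1 of 4), which leaves pairing open. Between cell types they correlated by −0.017 to 0.069 in control and 0.021 to 0.046 in c/chip mice. With same-numbered arrays of a genotype as a random block (consensus correlation −0.0112), the counts were 429, 25, 993, 704 and 13. With numbers 1 and 2 against 3 and 4 as a term the counts were 461, 29, 1049, 743 and 14. Of 140 named gene calls, 35 of 134 were lost with only the 2 groups, 13 with the immediate early covariate and 11 without the arrays in doubt, and 0 reversed in these fits. The other deposited table and probe name suffixes were planned as alternatives and not run, because the columns match no sample and the probe names carry no suffix. Signal over background was not given.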

Other observations

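The over-representation tests and their fits without 1 array, the tests of the immediate early list against handling, replicate number and sex and of genotype with the numbers held, and the test of c/chip MDPs against the axis between cell types were chosen only after the result was seen.

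The basophil and mast cell list was mixed between cell types in control mice. Of its 18 measured genes, Hdc was 2.52 higher in cMoPs (SE 0.269), Cpa3 was 2.996 lower (SE 0.368) and Gata2 was 1.74 lower (SE 0.378), and 15 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.157). In c/chip mice, the receptor gene Csf1r was 0.76 higher in cMoPs than in MDPs (SE 0.157, adjusted p = 0.0107). Cd79a, a B cell receptor component gene, was at 6.38 in c/chip MDP replicate 2 and at 3.57 to 3.70 in the other arrays of that group.

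Of 37 germline genes, 3 (8.11%) were called higher in c/chip MDPs against 1.25% of the other genes (one-sided Fisher's exact p = 0.0113, adjusted 0.0563 over 10 tests), and 2 (5.41%) in cMoPs against 0.06% (p = 2.80e-04, adjusted 0.0028), although the list as a whole did not pass. These counts rest on single arrays: over 16 fits without 1 array they were 1 to 3 in MDPs (p under 0.05 in 5 fits) and 0 to 2 in cMoPs (14 fits), 0 without control cMoP replicate 3 or 4. The tables argue against a segment around Dnmt1 that differs between the mouse lines, since 0 of the 13 other genes called in both cell types lie among the 200 neighbours on either side, and against sex, since 7 of 7 germline and meiosis genes stayed called with the Y-linked level as a covariate. The latter 7 include genes outside the list (Tex12, Stag3, Tex14 and Rpl39l), chosen after their values were seen. All of these were higher in c/chip cells, so they do not show how germline genes outside the list moved as a whole. A hypothesis is that reduced Dnmt1 may release germline promoters, but methylation was not measured here.

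The immediate early and stress list was lower in c/chip cells by 0.862 in MDPs and 0.744 in cMoPs on average, in 8 of 8 comparisons of arrays with the same number. It also differed between replicate numbers 1 and 2 and numbers 3 and 4, by 1.276 (exact permutation p = 0.0015 over 1296 arrangements). A session or day shared by these numbers could give such a difference. In control arrays of both cell types, numbers 1 and 2 had high Xist and numbers 3 and 4 low, so sex cannot be told apart there. In c/chip cMoPs, number 2, with low Xist like numbers 3 and 4, was at 7.116 against 5.662 and 5.353. Permuting genotype within cell type gave an exact p = 0.0580 over 4900 arrangements, and within cell type and these pairs of numbers 0.0015 over 1296. Same-numbered arrays had alike levels in MDPs and cMoPs (7.712 and 7.88 in control number 1, 6.495 and 6.005 in control number 3). All these permutations shuffled the cell types separately, so where such arrays share a source the p-values are too small. The 8 of 8 count and the SEs below have the same limit. The values argue against sex as the whole cause, since with the Y-linked level and these pairs of numbers as terms the genotype difference was −0.871 (SE 0.161), although with the Y-linked level alone it was −0.601 (SE 0.361). Handling of single arrays cannot be told apart from genotype, because no label records it and the within-group SD (0.728 in MDPs) was still 0.397 in cMoPs within the pairs of numbers (0.216 in MDPs).

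On the axis between cell types in control mice, c/chip MDPs lay towards cMoPs: with separate control MDP arrays on each side, the correlation across genes of the genotype and cell type differences was 0.174 or more in each of 6 splits. With shared controls it was 0.465, and 0.499 came from simulated data without any effect, so that value cannot be read. A shift of MDPs towards the cMoP profile may account for it, as may cMoPs within the gate. In cMoPs the lowest correlation was 0.019 over 6 splits, which leaves a shift open. Genes are not independent replicates here.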
